A study of Caenorhabditis elegans with 8 samples.

How the data were processed

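The series holds 8 small RNA libraries of Caenorhabditis elegans, 2 for each combination of genotype (N2 or rde-12(hj41)) and food (OP50 or HT115 with a sel-1 trigger). Per the labels' protocols, small RNA was enriched from total RNA, RNA of 20 to 26 nt was cut from a gel and treated with TAP, an enzyme that opens RNAs with a triphosphate end to adapter ligation, and indexed libraries were made with the ScriptMiner kit. TopHat 1.4.1, SAMtools and bedtools are named in the submitters' processing notes. How reads with several matches were assigned, the genome build, the annotation, the strand counted and the choice of genes are not given in the sources used here. Each of these could shift counts between similar, overlapping or antisense genes.

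The deposited gene table holds whole-number counts of small RNAs per gene, not normalized, for the 4 OP50 libraries. It has 1959 rows, of which 22 repeat another row with identical values, 7 of them in the ERGO-1 list below. These repeats of the same gene were counted once, leaving 1937 genes. Among them, 18 genes in 9 pairs have different IDs but identical counts in all 4 libraries, and were tested separately. Of these 4 fell and 4 rose, and 0 are named or in a gene list. These are a selection made before deposit, so totals over them are not whole-library depths. Of the gene IDs, 1900 matched a RefSeq gene table of assembly WBcel235, which was used for names and for which genes neighbour each other, and 37 kept their IDs. The deposited sel-1 table holds whole-number counts per region of sel-1 for the 4 sel-1 RNAi libraries, in 24 rows that form 2 blocks of 12 with the same libraries and regions. The file headers do not name what separates the blocks, so they are called first and second by their place. Gene counts of the sel-1 RNAi libraries, sel-1 counts of the OP50 libraries and counts for sel-1 and rde-12 as genes were not analysed here. The counts therefore do not check the mutation, give no background of sel-1 small RNAs on OP50 and allow no comparison of foods, no interaction and no scaling to microRNAs.

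Groups came from the sample labels. The comparisons, tests, gene lists and most alternatives were fixed before the data were examined. Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors between 0.987 and 1.03, filterByExpr, which removed 6 genes), with Benjamini-Hochberg adjustment over the 1931 remaining genes and a threshold of 0.05. The planned fit over all 8 libraries became a fit over the 4 OP50 libraries. Standard errors were taken as the absolute log2 change divided by the square root of the F statistic. Levels are counts relative to library size (CPM) scaled with TMM factors, as mean ± SD of 2 libraries. The 6 sel-1 counts per library were tested with edgeR at equal library sizes, because the planned offsets from library totals were not analysed here for these libraries. Their differences were also tested with two-sided exact permutation tests, on log2 of the count plus 1, which cannot go below 0.333. Shares of single libraries have Wilson 95% intervals. Gene lists with at least 5 tested members were compared with the other genes by camera (limma 3.58.1) with a preset correlation of 0.01.

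The lists were written from general knowledge and not taken from these samples, and the ERGO-1 list was not checked against published targets. They were ERGO-1 targets (29 genes, 26 tested), WAGO targets (4 tested), germline genes (16, 3 tested), sperm genes by name (23 tested) and RNAi factors (21, 1 tested). Lists of microRNAs, piRNAs and structural RNAs had 0 members among the rows used. Named genes are up to 12 falls and 12 rises with the largest log2 change among those past the threshold whose libraries do not overlap, a set of genes chosen in advance, and the 2 most changed of each list with at least 3 tested members. The last part was planned on a mean over both foods and was done on OP50. Other members of the lists are named to complete small counts or as neighbouring copies, after their values were seen.

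Replicates were compared before averaging. Counts of N2 replicates differed by more than sampling noise (chi-square per degree of freedom 3.50), as did those of rde-12 replicates (4.14), against 130 between genotypes, so no pair of replicates looked like a repeat deposit of the same library. That the libraries are separate biological samples rests on the labels alone. The biological coefficient of variation was 4.06%. On simulated data with the means and library sizes of the OP50 comparison over 1937 genes, the gene test called 72.0% of genes changed 1.25-fold. It called 92.0% at 1.5-fold and 100% at 2-fold and 4-fold, with 3 false calls among 185. The simulated genes all had the same spread, estimated from the real counts, and as many rises as falls. They do not show the error rate where genes differ in spread or falls are larger than rises. For the sel-1 counts, 300 simulated tables gave calls in 99.7% to 100% of lowered regions and in 4 to 6% of unchanged ones. These tables had log2 changes of −4 or −2 in the lowered regions, a spread set by hand, equal depth and regions drawn independently. They do not show the error rate where depth differs or the regions of a library move together.

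Alternatives were DESeq2 1.42.0, library totals, no filter, a filter at a mean of 10 CPM, the replicate number as a block, each library left out in turn, limma on log2 of the sel-1 count plus 0.5 or 5, and an estimated correlation in camera. Added after seeing the data were a test against a 1.5-fold change, upper-quartile factors, TMM factors from genes outside the ERGO-1 list, sel-1 counts scaled to the second-block trigger, identical rows of different genes counted once, and camera on ranks with a preset or an estimated correlation. Permutation tests were run in R, and tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.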

Results

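Small RNAs were sequenced from whole young adult Caenorhabditis elegans of 2 genotypes on 2 kinds of bacterial food. N2 is the standard wild-type strain, and rde-12(hj41) carries a mutation in the gene for RDE-12, a DEAD-box helicase that acts in RNA interference. Synchronised larvae were fed for 50 h at 20 °C either on OP50, the usual laboratory food, or on HT115 bacteria that express double-stranded RNA against part of sel-1 (the trigger). Each of the 4 combinations had 2 libraries, which the labels call biological samples. The p-values of tests per gene or per region rest on the spread between these samples. Those of camera, Fisher's exact test and the shuffles of neighbouring genes compare genes and do not measure that spread. The study asked how small RNAs made in response to an eaten trigger differ between wild-type and rde-12 animals. Counts by region of sel-1 were analysed for the 4 libraries from sel-1 RNAi food, and counts by gene for the 4 libraries from OP50. The gene counts summed to 4270098 and 4382256 in the N2 libraries and to 5563151 and 4354715 in the rde-12 libraries. The sel-1 counts summed to 764447 and 678330 in N2 and to 24884 and 33272 in rde-12. Genome positions are not printed, because the build behind the counts is not given in the sources used here.

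The first comparison asked how many sel-1 small RNAs the animals held while eating the trigger. In rde-12 animals, small RNAs against sel-1 were far scarcer than in wild type, and the loss was deepest upstream of the trigger. The sel-1 counts came in 2 blocks of the same 3 regions: upstream of the trigger, the trigger itself, and downstream of it. What separates the blocks is not given in the sources used here. In the first block, which held nearly all wild-type counts, upstream counts averaged 160076 ± 8215 per library in N2 and 2539.5 ± 484 in rde-12 (mean ± SD, n = 2 each), 63.0-fold lower. Trigger counts averaged 520338 ± 50174 in N2 and 13440.5 ± 2959 in rde-12, 38.7-fold lower. Downstream counts averaged 37311.5 ± 2454 in N2 and 7037 ± 1558 in rde-12, 5.30-fold lower. The log2 changes were −5.98 ± 0.364 (SE) upstream, −5.27 ± 0.396 in the trigger and −2.41 ± 0.275 downstream. With edgeR's quasi-likelihood test over the 6 region counts, Benjamini-Hochberg adjusted p was 8.24e-09, 4.44e-08 and 2.99e-06. The 6 counts come from the same libraries and can move together: in rde-12 all 3 first-block counts were lower in replicate 1. The test treats them as separate rows, so its p-values can be too small. Every rde-12 library lay below every N2 library in these 3 regions. A two-sided exact permutation test gave p = 0.33 for each, the smallest that 2 libraries against 2 allow. The total depth of these libraries is unknown, so the folds compare counts per library as deposited. The counts were also scaled to the second-block trigger count of the same library, a setting chosen after the data were seen. The first-block losses were then 105-fold upstream, 64.5-fold in the trigger and 8.84-fold downstream. This scaling takes the second-block trigger as unchanged by genotype and is not a measure of depth. That count was itself 1.66-fold higher in rde-12, and whether depth or genotype raised it is not known.

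**Figure D1:**
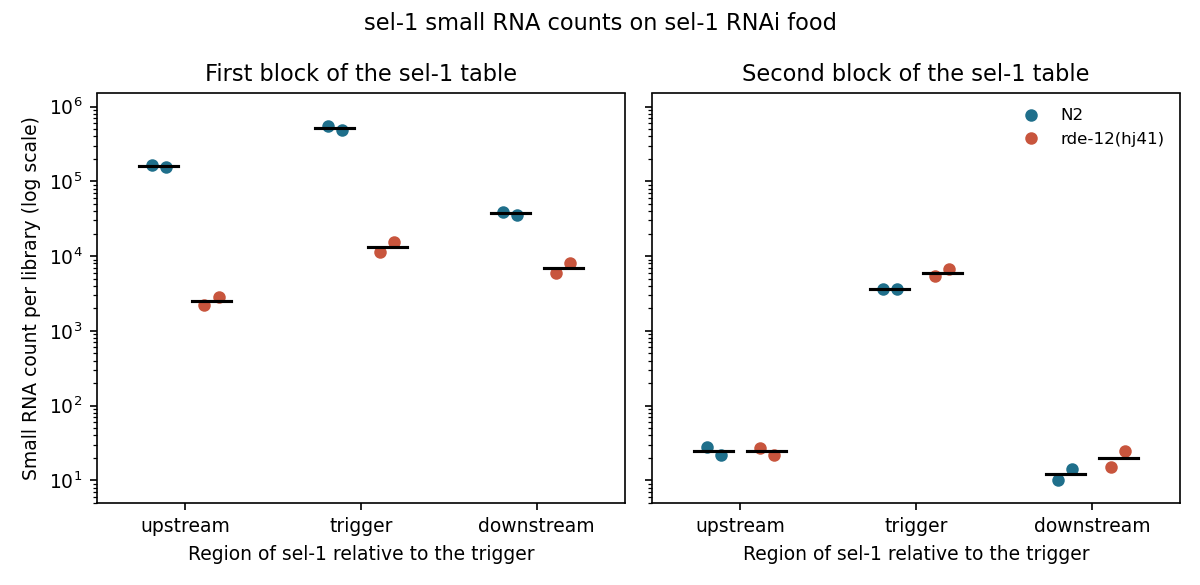
Small RNA counts per library (vertical axis, log scale) in the 3 regions of sel-1 (horizontal axis) for the first block (left) and the second block (right), on sel-1 RNAi food. Points are the 2 libraries of each genotype and bars their means; first-block upstream counts average 160076 in N2 and 2539.5 in rde-12, while second-block trigger counts average 3626 and 6016.5.

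The make-up of the first block also differed between genotypes by more than the spread between replicates. Upstream small RNAs made up 22.3% ± 0.749 (SD, n = 2) of the first block in N2 and 11.07% ± 0.300 in rde-12. The trigger held 72.5% ± 0.848 in N2 and 58.4% ± 0.171 in rde-12. Downstream small RNAs made up 5.203% ± 0.0991 in N2 and 30.6% ± 0.130 in rde-12, a difference of 25.4 percentage points. There were 0.233 ± 0.00337 downstream counts per upstream count in N2 and 2.76 ± 0.0867 in rde-12, an 11.9-fold higher ratio that does not depend on depth. For single libraries, the Wilson 95% interval of the downstream share ran from 5.08% to 5.18% and from 5.22% to 5.33% in N2. In rde-12 the intervals ran from 29.8% to 31.1% and from 30.1% to 31.2%. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No share overlapped between genotypes, and the two-sided exact permutation test again gave its smallest possible p of 0.33 for each.

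The second block held few small RNAs in either genotype, nearly all of them within the trigger, and trigger counts there were not lower in rde-12. Trigger counts averaged 3626 ± 49.5 in N2 and 6016.5 ± 926 in rde-12 (mean ± SD, n = 2 each), 1.66-fold higher in rde-12. The log2 change was 0.73 ± 0.230 (SE; edgeR adjusted p = 0.0121; exact permutation p = 0.33). The total depth of these libraries is unknown, so a difference in depth alone could give this rise. Upstream counts averaged 25.0 ± 4.24 in N2 and 24.5 ± 3.54 in rde-12 (log2 change −0.03 ± 0.392; edgeR adjusted p = 0.942), and the sign of this change turned without N2 replicate 1 (0.15) or without rde-12 replicate 2 (0.11). Downstream counts averaged 12 ± 2.83 and 20.0 ± 7.07 (log2 change 0.73 ± 0.474; edgeR adjusted p = 0.178), a difference not detectable at this depth with edgeR. Scaled to the second-block trigger, the log2 changes were −0.75 upstream (edgeR adjusted p = 0.104) and 0.00 downstream (adjusted p = 0.992). The second block made up 0.509% ± 0.0359 of all sel-1 counts in N2 and 20.95% ± 1.08 in rde-12. Each second-block trigger count came with 143 ± 11.9 first-block trigger counts in N2 and with 2.22 ± 0.150 in rde-12, a 64.5-fold difference. The call for the second-block trigger ended without N2 replicate 1 (log2 change 0.74, edgeR adjusted p = 0.371) or without N2 replicate 2 (0.72, adjusted p = 0.382). The second-block downstream counts passed the threshold with limma on log2 of the count plus 0.5 (log2 change 0.69, adjusted p = 0.0273).

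The other comparison asked how small RNAs against the animals' own genes differed between rde-12 and N2 on OP50, with no trigger eaten. Small RNAs fell against 25 of 26 measured genes listed as targets of the ERGO-1 pathway, with a median log2 change of −2.47. In this pathway an Argonaute protein starts the silencing of a set of endogenous transcripts. The list came from general knowledge and was not checked against published targets. Against fbxa-61 (Y119D3B.8), which encodes an F-box protein and is outside the ERGO-1 list fixed in advance, small RNAs fell 86.2-fold. Their level went from 313 ± 8.80 to 3.64 ± 0.533 CPM (mean ± SD, n = 2 each). CPM are counts scaled to the library's total over the tested genes. Rises were smaller, up to 3.64-fold for T16H12.2. In all, 268 of the 1931 genes tested fell and 267 rose in rde-12 at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. Of the falls, 65 exceeded 2-fold and 35 exceeded 4-fold, whereas 6 rises exceeded 2-fold. Most rises, 233, were under 1.5-fold, as were 166 of the falls. The libraries of the 2 genotypes did not overlap in any of the 535 called genes. This adds no support, because the calls were made on the same values. Of all 1931 genes tested, 1240 had libraries that did not overlap, where 33.3% of genes would by chance.

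These counts moved with the settings. With library totals in place of TMM factors 221 genes fell and 333 rose, and with upper-quartile factors 202 fell and 370 rose, so that rises made up 60.1% and 64.7% of calls against 49.9%. DESeq2 called 157 falls and 207 rises. Without rde-12 replicate 1 there were 175 falls and 165 rises. Tested against a change of 1.5-fold, 75 genes fell and 10 rose.

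Small RNAs against 25 of the 26 measured genes of the ERGO-1 list fell in rde-12, and none rose. The count was also 25 when adjusted over the list alone, 25 at an unadjusted p under 0.05 and 25 with DESeq2, with 0 rises in each. K02E2.6, a strongly targeted gene of this pathway, fell 18.6-fold, from 4806 ± 153 to 258 ± 16.6 CPM (log2 change −4.22 ± 0.0706 (SE), edgeR adjusted p = 1.44e-16). T08B6.2 fell 42.5-fold, from 486 ± 28.8 to 11.48 ± 0.828 CPM (log2 change −5.41 ± 0.0975, edgeR adjusted p = 2.65e-16). W04B5.2 fell 16.4-fold, Y17D7B.4 15.96-fold, F55C9.3 12.47-fold and E01G4.5 10.24-fold. Smaller losses were measured for E01G4.7, which fell 3.12-fold, and W05H12.2, which fell 3.36-fold. C18D4.6 did not pass the test, at 1002 ± 45.8 CPM in N2 and 1044 ± 4.54 in rde-12 (log2 change 0.06, edgeR adjusted p = 0.482). The median log2 change over the list was −2.47. Of the counts summed over the selected genes, the list held 4.598% ± 0.0720 in N2 and 0.865% ± 0.00931 in rde-12 (SD, n = 2). This share was 5.31-fold lower in rde-12, with an exact permutation p of 0.33. Against all other genes, camera with a preset correlation gave an adjusted p of 2.53e-143 for the list, and the adjusted p = 0.00986 with an estimated correlation. On ranks, chosen after the data were seen, the adjusted p = 0.114 with an estimated correlation. Some members lie close together or resemble each other, among them E01G4.5 and E01G4.7, W04B5.1 and W04B5.2, and ZK402.2, ZK402.3 and ZK402.5. Where reads matching such copies were counted is not known here, so their separate values are uncertain.

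**Figure D2:**
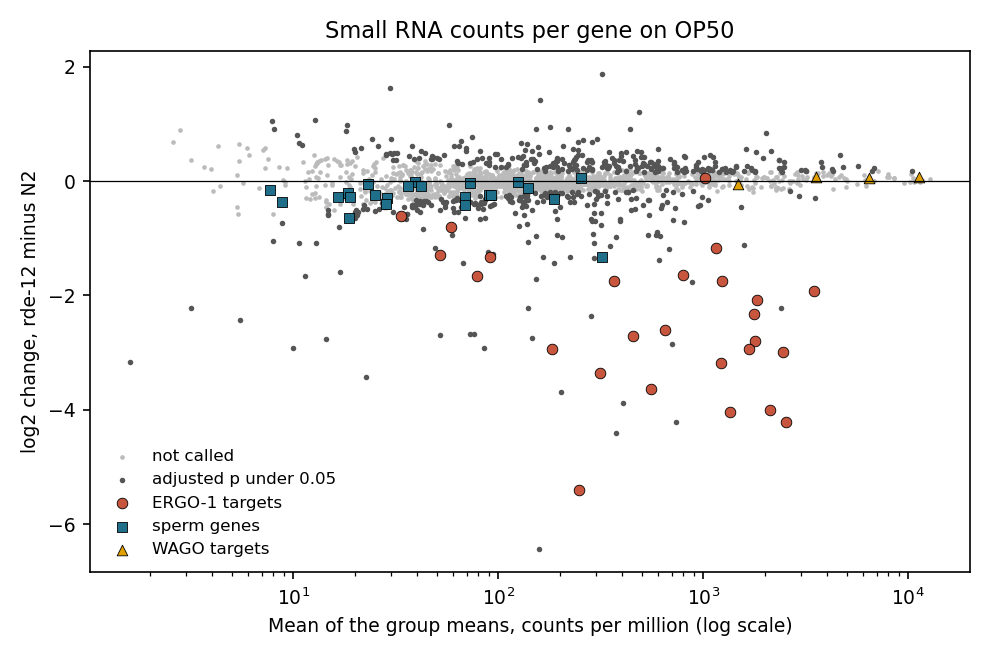
Log2 change in small RNA counts, rde-12 minus N2 (vertical axis), against the mean of the group means in CPM (horizontal axis, log scale) for the genes tested on OP50. Grey points were not called, dark points passed an adjusted p of 0.05, and the fixed lists are marked. In the ERGO-1 list 25 of 26 genes fell, with a median log2 change of −2.47, while the 4 WAGO targets lie between −0.05 and 0.07.

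Outside the ERGO-1 list, 20 genes fell more than 4-fold. Because the list was not checked against published targets, some of these genes may belong to the pathway. After fbxa-61 (log2 change −6.43 ± 0.118, edgeR adjusted p = 2.92e-16), the largest losses were at T28D6.4, from 714 ± 12.21 to 33.2 ± 5.91 CPM (−4.41 ± 0.0885, adjusted p = 7.24e-16), and at B0001.5, from 1392 ± 20.9 to 74.8 ± 0.731 (−4.22 ± 0.0680, adjusted p = 1.44e-16). Another 2 F-box genes were among the 12 largest falls. Small RNAs against fbxa-52 (F07G6.6) fell 14.7-fold and those against fbxa-46 (F52D2.8) 10.8-fold. The cuticlin-like gene cutl-10 (Y53H1B.1) fell 12.9-fold, from 374 ± 3.57 to 28.9 ± 3.28 CPM. The F-box genes belong to a large family of similar genes, so reads shared between members leave their separate values uncertain.

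Small RNAs against T16H12.2 rose from 138 ± 14.5 to 500 ± 33.6 CPM (log2 change 1.86 ± 0.0767, edgeR adjusted p = 1.02e-11). Those against hphd-1 (Y38F1A.6), an enzyme of propionate breakdown, rose 3.098-fold, from 14.5 ± 0.299 to 44.6 ± 4.67 (1.63 ± 0.143, adjusted p = 1.99e-07). C11D2.3 rose with a log2 change of 1.42 and the collagen gene col-111 (F29B9.9) with 1.20. Changes close to 2-fold were measured for irx-1 (C36F7.1), an Iroquois-type homeobox gene, at 0.98, and for the claudin-like gene clc-7 (C24H10.1), also at 0.98. C44C1.1 (1.06), F15A4.2 (1.05), Y71F9B.13 (0.95), F31C3.6 (0.92), afmd-2 (Y45F10A.3; 0.91) and ZK666.1 (0.91) completed the 12. Both F15A4.2 and ZK666.1 had few counts, between 3.896 and 12.7 CPM. The call for F15A4.2 ended without rde-12 replicate 2 (log2 change 0.76, adjusted p = 0.149) and with DESeq2 (adjusted p = 0.0894). That for ZK666.1 ended without N2 replicate 2 (adjusted p = 0.0621), without rde-12 replicate 1 (0.103) or 2 (0.0583), and with DESeq2 (0.137).

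**Figure D3:**
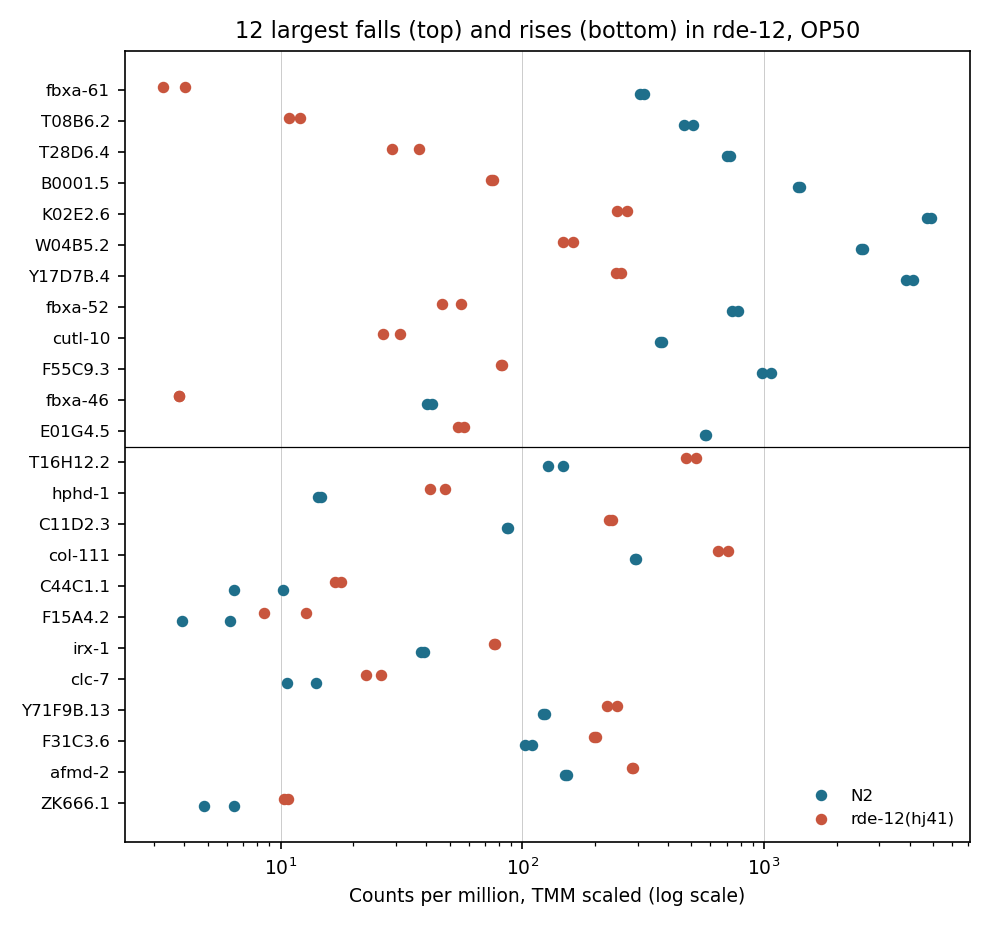
CPM scaled with TMM factors (horizontal axis, log scale) in each OP50 library for the 12 genes with the largest falls (top) and the 12 with the largest rises (bottom) in rde-12. Points are the 2 libraries per genotype; those of fbxa-61 average 313 in N2 and 3.64 in rde-12, those of T16H12.2 138 and 500.

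WAGO targets and germline genes did not pass the test. None of the 4 measured WAGO targets, genes silenced in the germline through worm-specific Argonautes, was called by edgeR or by DESeq2, and 0 had an unadjusted p under 0.05. Their levels were high. The BTB and MATH domain genes bath-45 (F29C12.5) and bath-13 (F40B1.1) held 11012 ± 205 and 1510 ± 32.9 CPM in N2 and 11498 ± 463 and 1456 ± 16.3 in rde-12 (log2 changes 0.06 ± 0.0631 and −0.05 ± 0.0550). The log2 changes of C38D9.2 and F37D6.3 were 0.07 and 0.05. Of the germline genes, 3 were measured and 0 were called by edgeR or DESeq2, with 1 at an unadjusted p under 0.05. That gene was glh-1 (T21G5.3), a Vasa-like helicase of germ granules, with a log2 change of 0.15 ± 0.0591 (edgeR adjusted p = 0.0759). It passed the threshold with library totals (0.17, adjusted p = 0.0173), with upper-quartile factors (0.20, 0.0179) and without rde-12 replicate 2 (0.17, 0.0265). The related glh-2 (C55B7.1) and pgl-3, a component of germ granules, had log2 changes of 0.10 and 0.08. Of the RNAi factor genes in the list, 1 was measured, the Argonaute gene sago-2, with a log2 change of 0.05 (edgeR adjusted p = 0.622). This 1 gene does not speak for RNAi genes as a group. Outside the list, and picked after its value was seen, eri-12 (B0001.6) lost small RNAs 2.51-fold (log2 change −1.33, edgeR adjusted p = 1.11e-10). Those against prg-2 (C01G5.2) did not pass the test (log2 change 0.01, edgeR adjusted p = 0.883).

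Small RNAs against 6 of 23 measured sperm genes fell in rde-12 and 0 rose, and 22 had a log2 change below 0, with a median of −0.25. Over all 1931 genes tested 268 fell and 267 rose, with a median log2 change of −0.02. The sperm genes were not compared with other genes of like level, so whether their lower values are particular to them was not tested. The number of sperm genes that fell was 6 when adjusted over the list alone. At an unadjusted p under 0.05, 8 fell and 0 rose, and with DESeq2 3 fell and 0 rose. The largest change was in spe-41 (K01A11.4), a TRP channel of sperm, which fell from 459 ± 2.89 to 182 ± 1.32 CPM (log2 change −1.34 ± 0.0599, edgeR adjusted p = 3.02e-11). The others were nspd-5 (F11G11.8; −0.65), nspd-4 (−0.43), nspd-1 (−0.40), ssp-16 (−0.31) and ssp-35 (−0.28), all members of families of nematode-specific sperm proteins whose similar sequences leave separate values uncertain. Against the other genes, camera did not call the sperm genes as a set (adjusted p = 0.210, and adjusted p = 0.412 with an estimated correlation). On ranks, also chosen after the data were seen, limma's camera called the list lower at the preset correlation (adjusted p = 0.00105), and the adjusted p = 0.114 with an estimated correlation. The number of falls was 3 without N2 replicate 1 and 3 without rde-12 replicate 1. The call for nspd-5 ended without N2 replicate 2 (adjusted p = 0.0518), without rde-12 replicate 1 (0.0714) and with DESeq2 (0.108).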

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

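Tests against 1.5-fold, upper-quartile factors, TMM factors outside the ERGO-1 list, scaling to the second-block trigger, identical rows counted once and camera on ranks were chosen after the data were seen. Of 576 alternative values 538 kept direction and side of the threshold (counts: within 1.5 times), 19 lost and 5 gained a call, 12 counts moved further and 2 changed sign; for the 33 named genes 409 of 427 held, 15 lost and 3 gained a call. The sign changes were in the uncalled second-block upstream change, which ranged from −0.19 to 0.15 with a library left out (0.15 without N2 replicate 1, 0.11 without rde-12 replicate 2). The first-block losses on sel-1 kept their calls in every alternative run on them, with losses of 105-, 64.5- and 8.84-fold when scaled to the second-block trigger. The region shares are counted above as kept, but with 2 libraries leaving out 1 always moves a mean by less than the SD, so this says nothing about their stability. With identical rows of different genes counted once 265 genes fell and 271 rose. ERGO-1 falls numbered 25 in each except the test against 1.5-fold, with 23. Falls numbered 157 with DESeq2 and 75 against 1.5-fold, where rises numbered 10; with each library left out in turn falls ranged from 175 to 304 and rises from 165 to 308. Sperm falls numbered 4 with library totals and with upper-quartile factors, 3 with DESeq2 and 1 against 1.5-fold, ranging from 3 to 7 with a library left out, and limma's camera on ranks gave the sperm list an adjusted p = 0.00105 at the preset correlation. On ranks with an estimated correlation the adjusted p = 0.114 for the sperm list and for the ERGO-1 list, which lost its call there. Germline calls numbered 1 with library totals and 1 with upper-quartile factors, ranging from 0 to 1. The second-block trigger change ranged from 0.56 to 0.88 with a library left out, and lost its call without either N2 library, each of which left N2 with 1 sample assumed to vary like rde-12. The second-block downstream change was 0.69 and passed with limma on the count plus 0.5. Groups share only replicate numbers: deviations of same-numbered libraries correlated at 0.02 over genes and 0.74 over the 6 sel-1 counts, with 2 pairs each. In the first-block counts and the second-block trigger, replicate 1 was the higher in N2 and the lower in rde-12. The value of 0.74 therefore does not show that same-numbered sel-1 libraries move together. With the replicate block 230 genes fell and 243 rose, and the second-block trigger change was 0.72 (adjusted p = 0.0839) and that of F15A4.2 was 1.06 (adjusted p = 0.0579), both past the threshold without it. Apart from the fewer samples or the higher bar in some settings, the cause of these shifts was not tested. Not run were the fits that need gene counts on sel-1 RNAi food, the OP50 background and microRNA or small RNA totals; a fit of only the 4 compared libraries equals the one reported. Depth limits the second-block counts outside the trigger, at 10 to 28 per library.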

Other observations

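The genes named here were picked after their values were seen, and of the tests in this part only the neighbour test was chosen before its result was seen. Among genes outside the ERGO-1 list, several abundant or well-known ones also lost small RNAs in rde-12 on OP50. Small RNAs against Y47H10A.5 fell from 3928 ± 13.7 to 842 ± 59.3 CPM (mean ± SD, n = 2; log2 change −2.22, edgeR adjusted p = 6.49e-14). Those against saeg-1 fell 3.38-fold, those against rimb-1, which encodes a protein of synaptic active zones, 5.103-fold, and those against trp-4, a mechanosensory channel gene, 2.61-fold. The chitin synthase gene chs-2 fell 6.69-fold, the acid ceramidase gene asah-1 6.41-fold and the glutathione transferase gene gsto-3 6.43-fold. Small RNAs against the transcription factor genes atf-4 (log2 change 0.68) and ces-2 (0.87) rose.

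F-box genes made up 3 of the 12 largest falls. Of 54 tested genes with F-box names, 11 fell and 8 rose, against 257 falls among 1877 other genes (two-sided Fisher's exact p = 0.163). Over 4-fold falls were found in 4 of the F-box genes and 31 of the others (Fisher's exact p = 0.0150). The first test gave no difference past the threshold, and the second concerns the size of change that drew attention to these genes. The sperm list, not called by camera on its usual statistic, was lower with limma's camera on ranks at the preset correlation (adjusted p = 0.00105). On ranks the adjusted p = 0.114 with an estimated correlation, so a lower level of the set stays open.

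The first pattern is the smaller loss of first-block sel-1 counts downstream of the trigger. A depth difference between libraries cannot give it as a whole, since the downstream to upstream ratio within a library was 11.9-fold higher in rde-12. If the blocks are the 2 strands, which is consistent with at most 1.03% of second-block counts outside the trigger against at least 26.9% of first-block counts, eaten double-stranded RNA reaching past the trigger would add downstream counts to both, yet the second block in rde-12 had 0.00327 downstream counts per trigger count against 0.523 in the first; this stays open because the blocks are unnamed. A fixed 6549 downstream counts per library that do not come from the trigger could also account for the gap between mean folds, although rde-12 replicate 1 held 5935 in all; with no OP50 sel-1 counts or depths analysed here this cannot be told apart from an effect of genotype on downstream small RNAs, which stays an untested hypothesis.

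The second pattern is the large number of small rises in rde-12. For the rises past 1.5-fold, 10 genes passed that test under all 5 scalings tried (TMM, library totals, upper quartile, TMM outside the ERGO-1 list and DESeq2-type factors). The choice among these scalings therefore does not account for them. Over the first 4 the median log2 change of all genes moved only between −0.022 and 0.031. All use the same gene counts, so they cannot exclude a larger shift in scale. For the rises as a whole, rises made up between 49.3% and 64.7% of calls over 4 of these scalings, and no spike-in or unrelated RNA class was analysed here that would fix the scale, so a scaling shift and a genotype effect cannot be told apart.

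The third pattern is the position of the genes that fell past 1.5-fold. Among 72 of them placed on the reference, 3 pairs were next to each other, against a median of 0 and a highest value of 5 in 100000 shuffles (permutation p = 0.0056): E01G4.5 with E01G4.7, ZK402.3 with ZK402.2 and ZK402.5 with ZK402.3. All of these genes belong to the ERGO-1 list, and both ZK402 pairs share ZK402.3. The shuffles took no account of the list, so the result does not extend to genes outside it. Reads shared between neighbouring copies may contribute to the falls and stay open: 67 of the 72 genes had no adjacent gene that fell past 1.5-fold, but 21 of the 72 had any adjacent gene among those counted, so this number decides nothing. Copies that lie elsewhere in the genome were not searched, and how reads with several matches were counted is not known here. A shared silencing of neighbouring genes that needs RDE-12 is an untested hypothesis.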
